A study of Mus musculus with 9 samples.

How the data were processed

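Gene expression was measured on 9 Illumina mouse BeadChip arrays, a 1-colour platform on which biotin-labelled cRNA made from total RNA is hybridised to beads that each carry 1 probe sequence. Every array held RNA from bone marrow-derived macrophages, which are macrophages grown from marrow cells in medium conditioned by L929 fibroblasts, a source of the growth factor M-CSF. Cells from C57Bl/6 mice, 3 per group, received vehicle or 1 of 2 TRAF-STOP compounds, numbered 6877002 and 6860766, for 1 h. They then received the agonistic CD40 antibody FGK45 at 25 ug/ml for 8 h, which gave 3 arrays in each of 3 groups. The labels number the mice 1 to 3 in every group and do not say in words whether an animal is shared between groups. The labels give no dose for either compound, and no array held macrophages without the antibody.

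Per the file headers, the first deposited table holds the bead-summary intensity of each probe, not normalised between arrays, and a detection p-value for each probe on each array. The intensity values were made with GenomeStudio 2011.1, per the submitters' processing notes, and the lowest values, between 78.2 and 89.8 on the 9 arrays, show that no background had been subtracted. The deposited detection p-value ranks a probe's intensity against the negative control beads of its array. The second deposited table holds log2 values that the authors normalised between arrays with R 3.1.3 and limma 3.22.7, per the submitters' processing notes, which do not name the function. These values ran from 4.18 to 14.39 and their median was 4.53 on each of the 9 arrays. They differed from the values computed here by at most 0.016 (median 0.00014), so their scale is log2 after background correction with an offset of 16 and quantile normalisation.

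The intensities were processed in R 4.3.3 with limma 3.58.1. The function neqc estimated the background from the detection p-values, subtracted it by the normexp model, added 16, made the distributions of the 9 arrays equal and took log2. Of 45281 probes, 16415 had a detection p under 0.05 on at least 3 of the 9 arrays and were kept. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378, and 34807 symbols matched the gene table by gene identifier, with 0 changed. Where a symbol had several detected probes (3439 genes), the probe with the highest mean over all arrays stood for the gene. This left 11406 features, 9081 with a symbol and 2325 probes without one, which are counted but not named.

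All 9 arrays entered one limma fit with a coefficient per group, so that the 3 groups shared one estimate of the spread, which followed the mean (eBayes with trend). Each pair of groups was compared by limma's two-sided moderated test with Benjamini-Hochberg adjustment over the 11406 features, and a gene counted as higher or lower at an adjusted p under 0.05. An F test asked whether a gene differed among the 3 groups. Log2 changes are first group minus second and are given with their standard error. A single gene compared by an exact permutation of 3 arrays against 3 cannot reach a p below 0.1, so gene-wise p-values rest on the shared spread of limma. The series' files and labels were the only data, and the design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

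The 29 gene lists covered CD40, TRAF and NF-kB components, NF-kB targets, cytokines, chemokines, leukocyte adhesion, interferon-stimulated genes, antigen presentation, alternative activation, cholesterol synthesis, LXR and lipid genes, NRF2 targets, heat shock proteins, the unfolded protein and ATF4 response, aryl hydrocarbon receptor targets, the cell cycle, p53 targets, glycolysis, proteases, immediate early genes, osteoclast genes, macrophage identity, housekeeping genes and markers of 7 other kinds of cell. They named 719 genes, of which 501 were tested, and 24 lists had the 5 tested genes required. Some genes stand on several lists, so the shifts of such lists are not fully separate evidence. Irf1 (NF-kB targets), Cxcl9 and Cxcl10 (chemokines) and Tap1 (antigen presentation) are also on the interferon list. The cytokine list also holds inflammatory mediators that are not cytokines, such as Nos2, Hdc and Edn1. A list's shift against all other genes was tested with camera at its preset correlation of 0.01, adjusted over the 24 lists, with an estimated correlation as an alternative. Limma's fry, which asks whether the members of a list moved themselves and not against other genes, was run on all 29 lists, with adjustment over them. Entries were matched by symbol and otherwise by a synonym, and the synonyms took Gpi1 to Pigq and Eno1 to Eno1b, which are other genes. Genes were named from the 12 with the largest rise and the 12 with the largest fall in each comparison. Those 12 had to be past the threshold with the same sign in all 3 mice. A fixed set of CD40 pathway and macrophage genes, and members of the lists past the threshold or with the smallest p, could also be named. The text does not name every gene that this rule allows.

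The labels give each array a mouse number, and the 3 numbers recur in every group, so arrays with the same number were read as coming from the same animal and as paired. The labels do not say in words that an animal is shared between groups, and the replicate numbers in the titles follow another order. Deviations from the group means correlated between arrays of the same mouse with a median r of -0.0049 over 9 pairs (range -0.15 to 0.16), against 0.030 over 18 pairs of different mice, so the values themselves show no sign of the pairing. The main fit has no mouse block. With mouse as a block the counts were 341, 335 and 497 for 6877002 against vehicle, 6860766 against vehicle and 6877002 against 6860766.

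The arrays lay on 4 slides. Slide 1 held vehicle replicate 1 and 6860766 replicates 1 and 2, slide 2 held vehicle replicate 2, slide 3 held 6877002 replicates 1 and 2 and 6860766 replicate 3, and slide 4 held 6877002 replicate 3 and vehicle replicate 3. All 3 arrays of 6877002 were therefore on slides 3 and 4. Deviations from the group means had a median r of 0.053 over 5 pairs of arrays on the same slide (range 0.039 to 0.16). Over 22 pairs on different slides the median was -0.010 (range -0.21 to 0.28). The main fit has no slide block. Each comparison is also given with slide as a block and within the slide that held both groups, which is a difference of 1 array against 1 or 2.

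The array count sets the precision. On simulated values with the real means and spread and 11406 features, the test recovered 42.1% of changes of 0.4 log2 units, 92.6% of 0.7 and 98.7% of 1 for 6877002 against vehicle, with 6.94% of its calls false. For 6860766 against vehicle the shares were 46.8%, 82.1% and 98.5%, with 6.37% false. For 6877002 against 6860766 they were 63.4%, 86.2% and 96.9%, with 2.98% false. The comparisons had the same simulated means, spread and array count and a single draw each, so their shares differ only by the draw. The simulated noise was independent between genes and arrays and held no slides, so the false shares may not hold for the real calls. The alternatives were mouse or slide as a block, no background correction, cyclic loess or median scaling, the authors' log2 values, other filters and probe choices, array weights, only the 6 arrays compared, leaving out each array or mouse, an adjusted p under 0.10 and the estimated correlation. Alternatives on the slide set, on arrays apart on the first principal component and on the glycolysis list without Pigq and Eno1b were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.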

Results

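Macrophages grown from the bone marrow of 3 mice per group were activated for 8 h through CD40, after 1 h with vehicle, 6877002 or 6860766. CD40 is a receptor of the tumour necrosis factor receptor family that signals through TRAF proteins. Both compounds belong to the TRAF-STOPs, small molecules made to block signalling from CD40 through TRAF6, and the study asks what they change in activated macrophages. Each group had 3 arrays, 1 per mouse. Between 15271 and 15926 of the 45281 probes on an array (33.7% to 35.2%) had signal over background, and the median raw intensity was 98.7 to 113. The deposited log2 values had a median of 4.53 on vehicle replicates 1, 2 and 3, on 6877002 replicates 1, 2 and 3 and on 6860766 replicates 1, 2 and 3. Arrays of the same group correlated at r = 0.993 to 0.996 across genes. The first principal component held 28.6% of the variance and put slides 3 and 4, which carried all of the 6877002 arrays, apart from slides 1 and 2.

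The first comparison asked what 6877002 changed relative to vehicle. Serpinb2, which encodes plasminogen activator inhibitor 2, rose 3.70-fold (log2 change 1.89 ± 0.18, SE, n = 3 arrays per group), and Ahrr, which encodes a repressor of the aryl hydrocarbon receptor, rose 2.76-fold (1.47 ± 0.11). Pdgfa, a growth factor for mesenchymal cells, rose 2.82-fold (1.49 ± 0.09), and Il7r, a chain of the IL-7 receptor, rose 2.30-fold (1.20 ± 0.08). Csf2, which encodes the growth factor GM-CSF, fell, with a log2 change of -1.13 ± 0.12, and so did Cx3cl1, a membrane-anchored chemokine, with -0.81 ± 0.12. These 6 genes had adjusted p-values from 1.62e-08 (Pdgfa) to 0.00035 (Cx3cl1) in limma and moved the same way in all 3 mice. The shared sign is not separate evidence, since the genes were selected on the same arrays. Other large rises included those of Spint1, a protease inhibitor (1.56 ± 0.16), of the nucleotide receptors P2ry13 (1.19 ± 0.12) and P2ry14 (1.17 ± 0.07), of the lysophosphatidic acid receptor Lpar6 (1.12 ± 0.09), of the MYC antagonist Mxd1 (1.07 ± 0.11), of Cd28 (1.06 ± 0.12) and of Rgs1, a regulator of G protein signalling (1.06 ± 0.07). Other falls included those of the STAT5-induced suppressor Cish (-0.66 ± 0.11) and of Itgal, the integrin chain of the leukocyte adhesion molecule LFA-1 (-0.48 ± 0.10).

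Of 11406 features, 341 passed the limma test between 6877002 and vehicle, 219 higher (64.2%) and 122 lower. All 341 had the same sign in the 3 mice, which selection on the same arrays makes likely, so this is not separate evidence. Of these, 25 changed by more than 1 log2 unit, and 1864 features had an unadjusted p under 0.05. With arrays scaled to a common median, 207 passed, 159 higher (76.8%) and 48 lower, and with array weights 627, 370 higher (59.0%) and 257 lower. With slide as a block 229 passed, 171 of them among the 341, and all 341 kept their sign. The count was 167 without 6877002 replicate 1, 183 without 6877002 replicate 2, 198 without vehicle replicate 2, 208 without vehicle replicate 1 and 653 without 6860766 replicate 3, an array that enters this comparison only through the shared spread, and it was 147 without mouse 1 and 127 without mouse 2.

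Interferon-stimulated genes, which encode antiviral effectors, were higher under 6877002. Of 38 tested, 14 rose, 0 fell and 24 did not pass (28 rose adjusted over the list alone), and 37 of the 38 values were positive. The list mean was 0.32 (95% confidence interval 0.16 to 0.48), with a camera adjusted p of 1.78e-24 and an adjusted p = 0.085 with an estimated correlation, the highest of its 30 alternatives. Ifit2, an inhibitor of viral translation, rose by 0.68 ± 0.08, Cmpk2, a mitochondrial nucleotide kinase, by 0.72 ± 0.10, Oasl1, an antiviral regulator, by 0.75 ± 0.11, and the transcription factor Irf1 by 0.49 ± 0.07. These 4 were among 7 members that passed whichever array was left out. Without 6877002 replicate 1, 8 of the 14 still passed, and without vehicle replicate 1, 9. The list mean was 0.25 (0.12 to 0.38) with slide as a block and 0.24 within slide 4.

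Antigen presentation and co-stimulation genes had 6 rises and 0 falls among 24 tested (10 and 1 adjusted over the list alone), with a list mean of 0.21 (0.12 to 0.30) and a camera adjusted p of 2.65e-06. The co-stimulatory ligand Cd86 rose by 0.74 ± 0.10, the class II chain H2-Aa by 0.69 ± 0.10, and Ciita, the transactivator of class II genes, by 0.84 ± 0.16. The mean was 0.18 with slide as a block and 0.19 within slide 4. Of 5 aryl hydrocarbon receptor targets tested, 4 rose (4 adjusted over the list alone), with a mean of 0.89 (0.74 to 1.05), or 0.55 without background correction, and a camera adjusted p of 7.56e-08. Ahrr and Serpinb2 passed whichever array was left out. Those 2 were the only ones to pass without vehicle replicate 1 or without 6877002 replicate 1. The mean was 0.92 with slide as a block and 0.86 within slide 4. Unfolded protein and ATF4 response genes had 5 rises among 33 tested (8 and 1 fall adjusted over the list alone), a mean of 0.12 (0.068 to 0.18) and a camera adjusted p of 0.00078. Chac1, which degrades glutathione, rose by 0.91 ± 0.09 and the pseudokinase Trib3 by 0.69 ± 0.09, while 3 of the 5 passed without vehicle replicate 1, vehicle replicate 3 or 6877002 replicate 2, and 2 without vehicle replicate 2 or 6877002 replicate 1. The mean was 0.13 with slide as a block and 0.12 within slide 4. These 3 lists also passed camera with an estimated correlation, with adjusted p-values of 0.039, 0.038 and 0.039 in the order given.

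**Figure D1:**
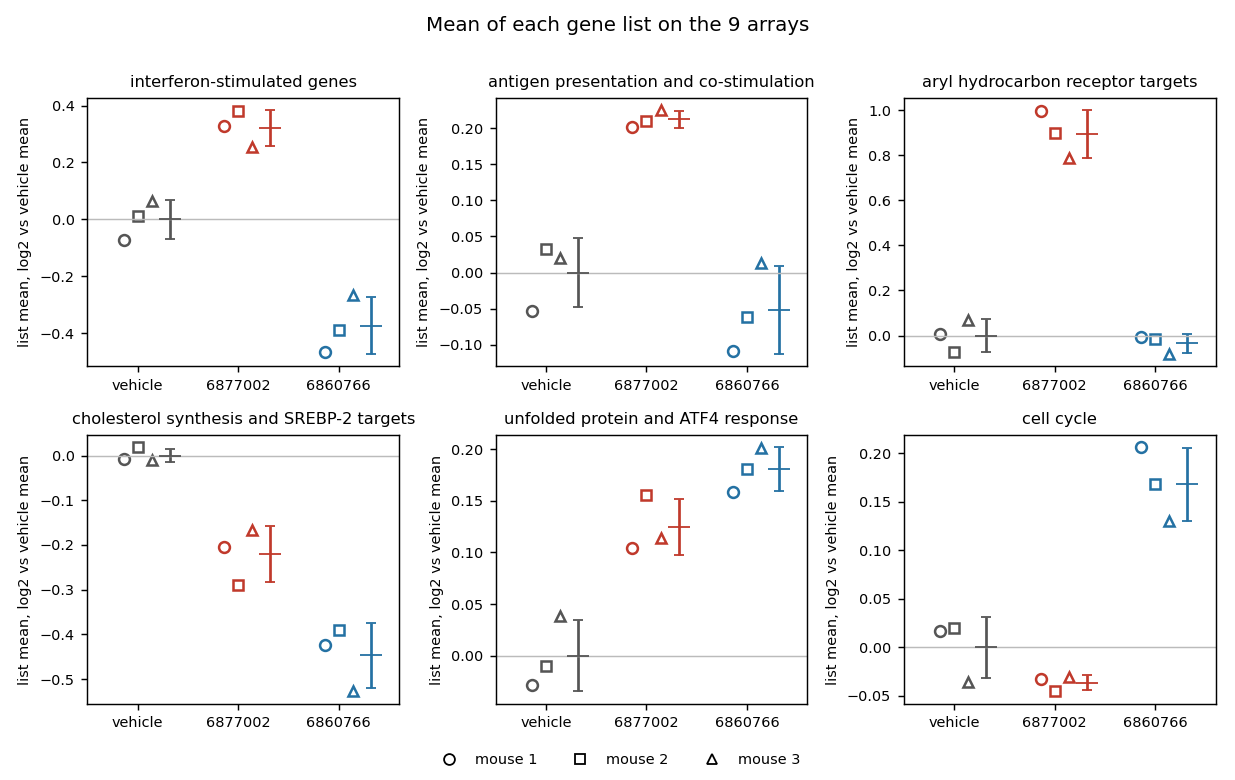
Mean log2 value of 6 gene lists on each of the 9 arrays, relative to the vehicle mean, with marker shapes for the 3 mice and bars for mean ± SD of the 3 arrays of a group. The interferon list averaged 0.32 above vehicle under 6877002 and -0.37 under 6860766, and the cholesterol list -0.22 and -0.45.

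Genes of cholesterol synthesis were lower under 6877002. Of 19 tested, 6 fell, 0 rose and 13 did not pass (11 fell adjusted over the list alone), and the mean was -0.22 (-0.33 to -0.11), with a camera adjusted p of 1.17e-08 and an adjusted p = 0.115 with an estimated correlation, the highest of its 30 alternatives. Lss, which makes lanosterol, fell by 0.42 on the log2 scale (SE 0.08) and passed whichever array was left out. The number of the 6 that passed was 1 without 6877002 replicate 1, 1 without 6877002 replicate 2, 2 without vehicle replicate 2, 3 without vehicle replicate 3 and 3 without 6877002 replicate 3. The mean was -0.16 (-0.30 to -0.02) with slide as a block and -0.19 within slide 4. Glycolysis and hypoxia genes averaged -0.14 (-0.30 to 0.016) over 27 tested, with 1 fall (1 rise and 2 falls adjusted over the list alone) and a camera adjusted p of 0.0035, while fry gave an adjusted p of 0.152. This call held in 26 of 31 alternatives, and the highest was an adjusted p = 0.505 with an estimated correlation. It was also lost in camera without 6877002 replicate 1 (mean -0.079, adjusted p = 0.12), with slide (-0.078, 0.18) or slide set (-0.087, 0.11) as a block and on slides 3 and 4 alone (-0.090, 0.18), and the mean within slide 4 was -0.035. A synonym had matched the list's entry Gpi1 to Pigq, a gene of GPI anchor synthesis, and Eno1 to Eno1b, and without these 2 the mean was -0.15 over 25 and the camera adjusted p 0.0028.

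Genes of the list of cytokines and mediators went both ways under 6877002. Of 26 tested, 3 rose and 5 fell (4 and 5 adjusted over the list alone), and the list as a whole did not shift (mean -0.019, camera adjusted p = 0.60). Il1rn, the IL-1 receptor antagonist, rose by 0.74 ± 0.10 and Nos2, the inducible nitric oxide synthase, by 0.80 ± 0.14. Il1a, an alarmin, changed by -0.56 ± 0.09 and Inhba, the activin A subunit, by -0.79 ± 0.13, in the same direction as Csf2. These 5 passed whichever array was left out, while without vehicle replicate 1 or 6877002 replicate 1 the 8 calls became 5. Chemokines had 2 falls among 18 tested (2 adjusted over the list alone), those of Cx3cl1 and of Ccl17, a ligand of CCR4 (-0.60 ± 0.12), and a mean of -0.046 (camera adjusted p = 0.60).

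The second comparison asked what 6860766 changed relative to vehicle. Cxcl10, an interferon-induced chemokine, had a log2 change of -1.12 ± 0.07 (n = 3 arrays per group), Ch25h, which makes 25-hydroxycholesterol, one of -1.04 ± 0.11, and Hdc, which makes histamine, one of -0.85 ± 0.09. Lss, which makes lanosterol, changed by -0.77 ± 0.08 and Fdps, which makes farnesyl diphosphate, by -0.70 ± 0.07. Il7r rose 1.79-fold (0.84 ± 0.08), Chac1 rose 1.72-fold (0.78 ± 0.09) and Pdgfa rose 1.66-fold (0.73 ± 0.09). These 8 genes had adjusted p-values from 1.53e-08 (Cxcl10) to 0.00012 (Pdgfa) in limma and moved the same way in all 3 mice. Again the shared sign is not separate evidence, as selection was on the same arrays. Other large changes included those of the cytokine signalling suppressor Socs1 (-0.82 ± 0.14), of Slfn1, a growth regulator of T cells (-0.82 ± 0.14), of Cx3cl1 (-0.97 ± 0.12), of Gstt4, a glutathione transferase (-1.03 ± 0.16), of Plau, which encodes urokinase (0.79 ± 0.10), and of the membrane protein Emp1 (0.69 ± 0.09).

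In total 328 features passed the limma test between 6860766 and vehicle, 124 higher (37.8%) and 204 lower. All had the same sign in the 3 mice, which selection on the same arrays again makes likely. Of these, 5 changed by more than 1 log2 unit, and 1452 features had an unadjusted p under 0.05. With median scaling 167 passed, 86 higher (51.5%) and 81 lower. With slide as a block 311 passed, 237 of them among the 328. The count was 168 without vehicle replicate 2, 205 without 6860766 replicate 2, 128 without mouse 1 and 106 without mouse 2.

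Interferon-stimulated genes fell under 6860766 in 22 of 38 cases, 0 rose and 16 did not pass (30 fell adjusted over the list alone). The mean was -0.37 (-0.53 to -0.22), with a camera adjusted p of 6.14e-36 that remained under the threshold with an estimated correlation (adjusted p = 0.033, the highest of its 31 alternatives). Besides Cxcl10, the interferon-inducible GTPase Igtp changed by -0.72 ± 0.07, the ISG15 protease Usp18 by -0.61 ± 0.07, and the dynamin-like antiviral proteins Mx1 by -0.71 ± 0.11 and Mx2 by -0.60 ± 0.09. Of the 22, 10 passed whichever array was left out, 11 passed without vehicle replicate 2 and 14 without 6860766 replicate 2. The mean was -0.36 with slide as a block and -0.35 within slide 1.

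Cholesterol synthesis genes fell in 10 of 19 cases, 0 rose and 9 did not pass (15 fell adjusted over the list alone), and 19 of 19 values were negative. The mean was -0.45 (-0.56 to -0.34), with a camera adjusted p of 2.90e-26 and one of 0.021 with an estimated correlation, the highest of its 31 alternatives. Besides Lss and Fdps, the sterol dehydrogenase Nsdhl changed by -0.82 ± 0.11, Hsd17b7 by -0.73 ± 0.08, the lanosterol demethylase Cyp51 by -0.69 ± 0.10 and the squalene epoxidase Sqle by -0.46 ± 0.07, and 9 of the 10 passed whichever array was left out. The mean was -0.42 with slide as a block and -0.40 within slide 1.

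Of 26 cytokine and mediator genes tested, 9 fell under 6860766 and 0 rose (14 and 1 adjusted over the list alone). The mean was -0.26 (-0.42 to -0.10), with a camera adjusted p of 2.70e-10 and one of 0.033 with an estimated correlation. Il15, a growth factor for natural killer cells, changed by -0.52 ± 0.08, the IL-12 subunit Il12a by -0.73 ± 0.14 and Csf2 by -0.79 ± 0.12. Of the 9, 4 passed without vehicle replicate 2 and 5 without 6860766 replicate 2. The mean was -0.29 with slide as a block, -0.34 within slide 1 and -0.074 on slides 3 and 4 alone, where the camera adjusted p of 0.089 was the highest of its 31 alternatives. Chemokines had 5 falls and 0 rises among 18 tested (6 and 1 adjusted over the list alone), a mean of -0.23 (-0.34 to -0.12), a camera adjusted p of 1.99e-05 and an adjusted p = 0.058 with an estimated correlation. Cxcl10, Cx3cl1 and Ccl17 (-0.63 ± 0.12) were the 3 that passed whichever array was left out, and 3 of the 5 passed without 6860766 replicate 2 or without vehicle replicate 3. Among the 5, Cxcl9 and Cxcl10 also stand on the interferon list. The chemokine mean was -0.21 with slide as a block and -0.21 within slide 1, and the highest camera adjusted p of its 31 alternatives was 0.135, on slides 3 and 4 alone.

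Unfolded protein and ATF4 response genes had 5 rises and 0 falls among 33 tested under 6860766 (10 and 0 adjusted over the list alone), a mean of 0.18 (0.12 to 0.24), a camera adjusted p of 1.27e-08 and one of 0.011 with an estimated correlation. Besides Chac1, Trib3 rose by 0.69 ± 0.09, the asparagine synthetase Asns by 0.48 ± 0.07 and the serine synthesis enzyme Psat1 by 0.43 ± 0.08. The mean was 0.20 with slide as a block and 0.20 within slide 1. Cell cycle genes had 5 rises and 0 falls among 32 tested (14 and 1 adjusted over the list alone), a mean of 0.17 (0.11 to 0.23), a camera adjusted p of 1.36e-07 and one of 0.033 with an estimated correlation. Ccnd1, which encodes cyclin D1, rose by 0.64 ± 0.11, and 1 of the 5 passed without vehicle replicate 1, vehicle replicate 2 or 6860766 replicate 2, and 2 without 6860766 replicate 1. The cell cycle mean was 0.16 with slide as a block, 0.17 within slide 1 and 0.11 on slides 3 and 4 alone.

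Glycolysis and hypoxia genes had 3 falls among 27 tested under 6860766 (3 adjusted over the list alone), a mean of -0.14 (-0.30 to 0.012), a camera adjusted p of 0.00059 (0.00087 without Pigq and Eno1b), one of 0.139 in fry and an adjusted p = 0.292 with an estimated correlation, the highest of its 32 alternatives. The lactate transporter Slc16a3 changed by -0.69 ± 0.13, and 1 of the 3 passed without vehicle replicate 2. The mean was -0.14 with slide as a block, -0.17 within slide 1 and -0.094 without background correction. NF-kB target genes had 1 fall among 32 tested (2 adjusted over the list alone) and a mean of -0.065 (-0.13 to -0.00021), with a camera adjusted p of 0.046, an adjusted p = 0.128 with an estimated correlation and one of 0.083 in fry. This call held in 21 of 31 alternatives, and the highest camera adjusted p was 0.865, on slides 3 and 4 alone (mean -0.012). That p was 0.12 without vehicle replicate 1, 0.071 without vehicle replicate 3, 0.26 without 6860766 replicate 1, 0.092 without 6860766 replicate 2, 0.051 without 6877002 replicate 3, 0.34 without mouse 1, 0.16 without mouse 2 and 0.071 over features detected on all 9 arrays. The mean was -0.078 with slide as a block, -0.11 within slide 1, -0.036 without mouse 1 and -0.099 without mouse 3.

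The third comparison set the compounds against each other, both added for 1 h before the antibody at doses the labels do not give. Serpinb2 was 5.33-fold higher with 6877002 than with 6860766 (log2 difference 2.42 ± 0.18, n = 3 arrays per group), Ahrr 2.48-fold higher (1.31 ± 0.11), Cxcl10 2.40-fold higher (1.26 ± 0.07) and Nos2 2.40-fold higher (1.26 ± 0.14). Gm4951, an interferon-inducible GTPase, was 3.07-fold higher (1.62 ± 0.13), P2ry13 2.82-fold higher (1.49 ± 0.12) and Ch25h 2.55-fold higher (1.35 ± 0.11). The mitotic genes Kif2c (-0.65 ± 0.11) and Cdc20 (-0.57 ± 0.08) were lower with 6877002. The adjusted p-values of these 9 genes ran from 2.01e-09 (Cxcl10) to 0.00075 (Kif2c) in limma, and each had the same sign in the 3 mice. In all, 516 features passed, 380 higher (73.6%) and 136 lower with 6877002. The sign was the same in the 3 mice for 514 of the 516, which selection on the same arrays again makes likely. Of these, 36 differed by more than 1 log2 unit, and 1903 features had an unadjusted p under 0.05. With median scaling 307 passed, 223 higher (72.6%) and 84 lower, and with array weights 1132, 637 higher (56.3%) and 495 lower. The share higher was largest without mouse 2, where 193 passed, 185 higher (95.9%) and 8 lower. With slide as a block 459 passed, 360 of them among the 516. The count was 315 without 6877002 replicate 1, 319 without 6877002 replicate 2, 332 without 6860766 replicate 2 and 1062 without 6860766 replicate 3.

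Of 38 interferon-stimulated genes, 34 were higher with 6877002 than with 6860766, 0 lower and 4 did not pass (36 higher adjusted over the list alone), and all 38 values were positive. The mean difference was 0.70 (0.54 to 0.85), with a camera adjusted p of 6.13e-66 and one of 0.016 with an estimated correlation, the highest of its 30 alternatives. Mx1 differed by 1.27 ± 0.11, Isg20, an RNA exonuclease, by 1.19 ± 0.10, Mx2 by 1.13 ± 0.09 and Igtp by 1.02 ± 0.07, and 31 of the 34 passed whichever array was left out. The mean was 0.61 (0.49 to 0.74) with slide as a block and 0.62 within slide 3. Antigen presentation genes were higher in 7 of 24 cases (12 adjusted over the list alone), with a mean of 0.26 (0.17 to 0.35), a camera adjusted p of 8.91e-11 and examples in Cd86 (0.95 ± 0.10), the peptide transporter subunit Tap1 (0.59 ± 0.08) and H2-Aa (0.49 ± 0.10). Tap1 also stands on the interferon list. The mean of the antigen presentation genes was 0.20 with slide as a block and 0.19 within slide 3. Aryl hydrocarbon receptor targets were higher in 3 of 5 cases (4 adjusted over the list alone), with a mean of 0.93 (0.77 to 1.1), or 0.56 without background correction, and a camera adjusted p of 4.91e-07. Their mean was 0.98 with slide as a block and 1.03 within slide 3.

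Cell cycle genes were lower with 6877002 than with 6860766 in 10 of 32 cases and higher in 0 (15 and 2 adjusted over the list alone), with a mean of -0.20 (-0.26 to -0.15) and a camera adjusted p of 2.36e-08. Kif22, a mitotic kinesin, differed by -0.55 ± 0.08 and Uhrf1, which maintains DNA methylation, by -0.44 ± 0.08. Of the 10, 4 passed without 6877002 replicate 1, 4 without 6860766 replicate 2, 5 without 6877002 replicate 2 and 6 without 6860766 replicate 1. The mean was -0.19 with slide as a block and -0.17 within slide 3. Macrophage identity genes were higher in 3 of 26 cases (4 adjusted over the list alone), with a mean of 0.12 (0.088 to 0.15), a camera adjusted p of 0.0012 and examples in the Fc receptor Fcgr1 (0.95 ± 0.10) and the receptor kinase Axl (0.40 ± 0.08). Their mean was 0.13 with slide as a block and 0.11 within slide 3. NF-kB target genes were higher in 3 of 32 cases (4 adjusted over the list alone), with a mean of 0.11 (0.042 to 0.17) and a camera adjusted p of 0.0031. Irf1, which also stands on the interferon list, differed by 0.45 ± 0.07. The NF-kB list mean was 0.084 with slide as a block and 0.053 within slide 3. Its mean was 0.059 with median scaling and 0.055 on slides 3 and 4 alone, where its camera adjusted p of 0.21 was the highest of 30 alternatives.

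Cholesterol synthesis genes were higher with 6877002 than with 6860766 in 5 of 19 cases (10 adjusted over the list alone), with a mean of 0.23 (0.12 to 0.34), a camera adjusted p of 1.20e-07 and an adjusted p = 0.099 with an estimated correlation, the highest of its 30 alternatives. Fdps differed by 0.40 ± 0.07, and the number of the 5 that passed was 1 without 6877002 replicate 3, 2 without 6877002 replicate 2 and 3 without 6877002 replicate 1 or 6860766 replicate 2. The mean was 0.26 with slide as a block and 0.28 within slide 3. Cytokine and mediator genes were higher in 7 of 26 cases (10 and 1 lower adjusted over the list alone), with a mean of 0.24 (0.08 to 0.40). The camera adjusted p was 3.53e-05, and 0.088 with an estimated correlation, the highest of its 30 alternatives. Il15 differed by 0.93 ± 0.08 and the IL-12 family subunit Il27 by 0.80 ± 0.12. The cytokine mean was 0.18 with slide as a block, 0.13 within slide 3 and 0.10 on slides 3 and 4 alone, where the call was also lost (camera adjusted p = 0.065), so it held in 28 of 30 alternatives. Chemokines were higher in 4 of 18 cases (5 adjusted over the list alone), with a mean of 0.18 (0.077 to 0.29), a camera adjusted p of 0.0050 and an adjusted p = 0.160 with an estimated correlation. Their call held in 25 of 30 alternatives, and in camera it was also lost with slide as a block (mean 0.12, adjusted p = 0.082), with slide set as a block (0.14, 0.053), without mouse 2 (0.14, 0.055) and on slides 3 and 4 alone (0.11, and 0.37, the highest). The mean within slide 3 was 0.12, and the number passing without 6860766 replicate 2 was 2. Among the 4 chemokines called, Cxcl9 and Cxcl10 also stand on the interferon list. The other lists called here passed camera with an estimated correlation.

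**Figure D2:**
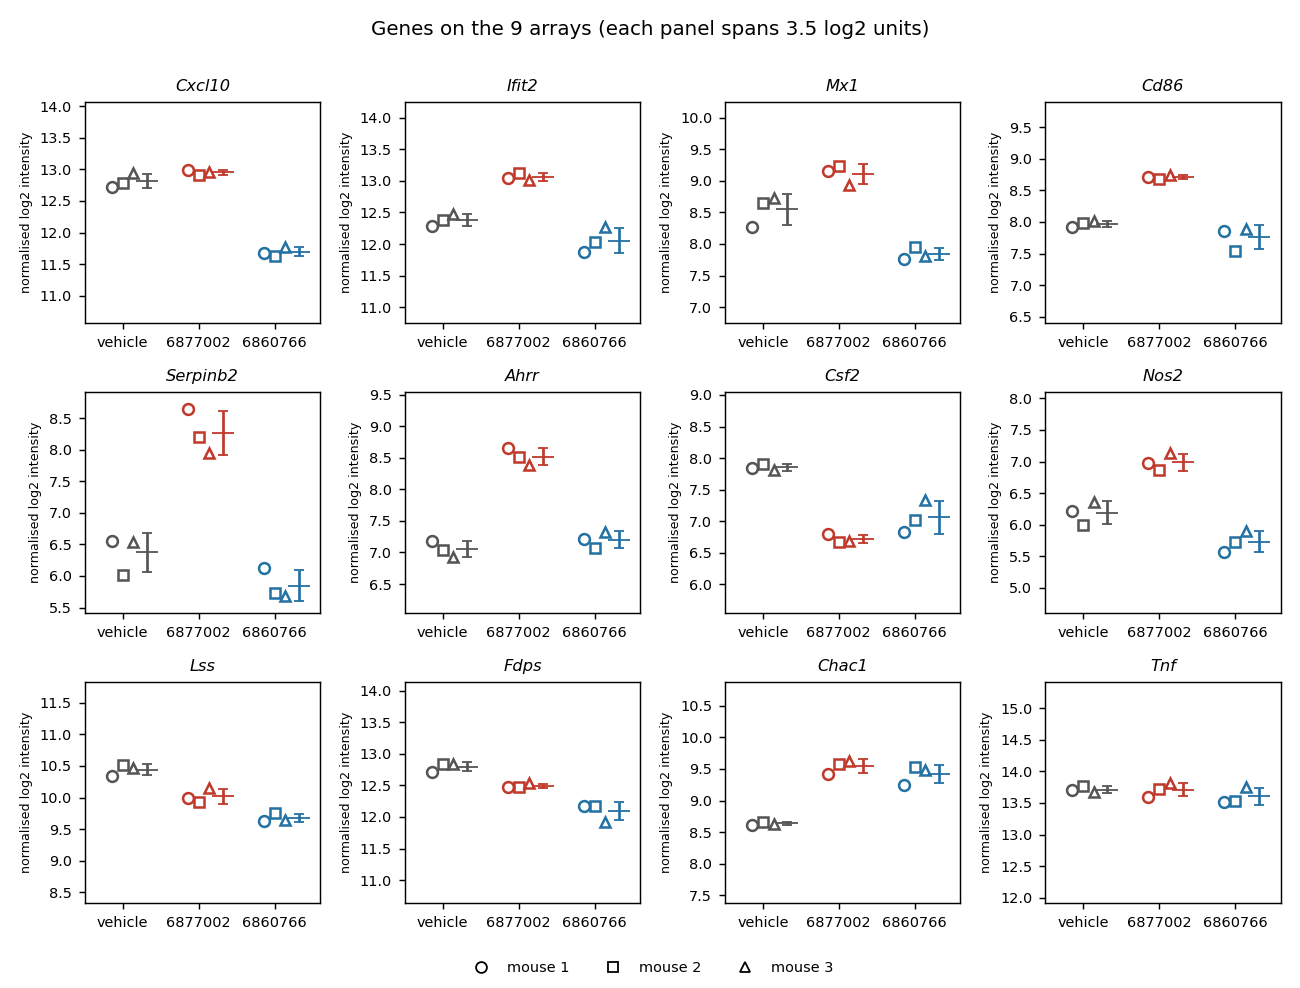
Normalised log2 intensity of 12 genes on the 9 arrays, by group, with marker shapes for the 3 mice and bars for mean ± SD of the 3 arrays of a group. Serpinb2 averaged 6.37 ± 0.31 with vehicle, 8.26 ± 0.35 with 6877002 and 5.85 ± 0.25 with 6860766. Tnf, which lay high on the scale, averaged 13.71, 13.71 and 13.60.

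For several changes no gene-wise difference between the compounds passed limma. The difference between 6877002 and 6860766 was 0.12 for Chac1 (95% confidence interval -0.06 to 0.30), -0.13 for Asns (-0.28 to 0.01), -0.05 for Plin2, which coats lipid droplets (-0.23 to 0.14), 0.02 for Plau (-0.19 to 0.24), 0.17 for Cx3cl1 (-0.08 to 0.41) and 0.04 for Ccl17 (-0.22 to 0.29). For the unfolded protein and ATF4 list it was -0.056 (-0.11 to 0.00046, camera adjusted p = 0.168), with 7 of 33 members positive and a negative mean in 3 of 3 mice, and the list passed fry (adjusted p = 0.038). None of the 33 members of that list passed limma between the compounds, with 0 adjusted over the list alone. These intervals bound the differences and do not show that the compounds act alike.

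In limma's F test 691 features differed among the 3 groups (458 without 6877002 replicate 1 and 1248 without 6860766 replicate 3). The calls against vehicle, made over all 11406 features, were set beside each other. Higher under both compounds were 39 features, where independent lists of these sizes would share 2.38, and lower under both were 45 (2.18). The former include Chac1, Trib3, Plin2, the cholesterol ester hydrolase Nceh1 (0.38 ± 0.07 and 0.42 ± 0.07), Plau, Il7r, Pdgfa and Ccnd1, and the latter Lss, Csf2, Cx3cl1 and Ccl17. Another 31 features were higher under 6877002 and lower under 6860766 (3.92 for independent lists), among them Mx2, Isg20 and Ifit3, and 0 went the other way (1.33). Unchanged groups simulated against the same 3 vehicle arrays shared 0 calls in each class, which does not show how much the shared arrays add to an overlap where effects are present. Across genes, which are not independent replicates, the log2 changes against vehicle correlated at r = 0.384 (Spearman's rho 0.395). Simulated unchanged groups that share controls gave a mean r of 0.499 (0.479 to 0.518 over 100 simulations). The covariance was 0.0133 against a simulated 0.00837. The r was 0.220 without 6860766 replicate 3 and 0.507 without vehicle replicate 3. Leaving out each array in turn gave r a jackknife standard error of 0.2125. The difference of r from the simulated mean, -0.115, is smaller in size than this error. The comparison therefore cannot tell whether r lies below the simulated value. Part of the overlap may come from the shared vehicle arrays, which are too few to split.

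**Figure D3:**
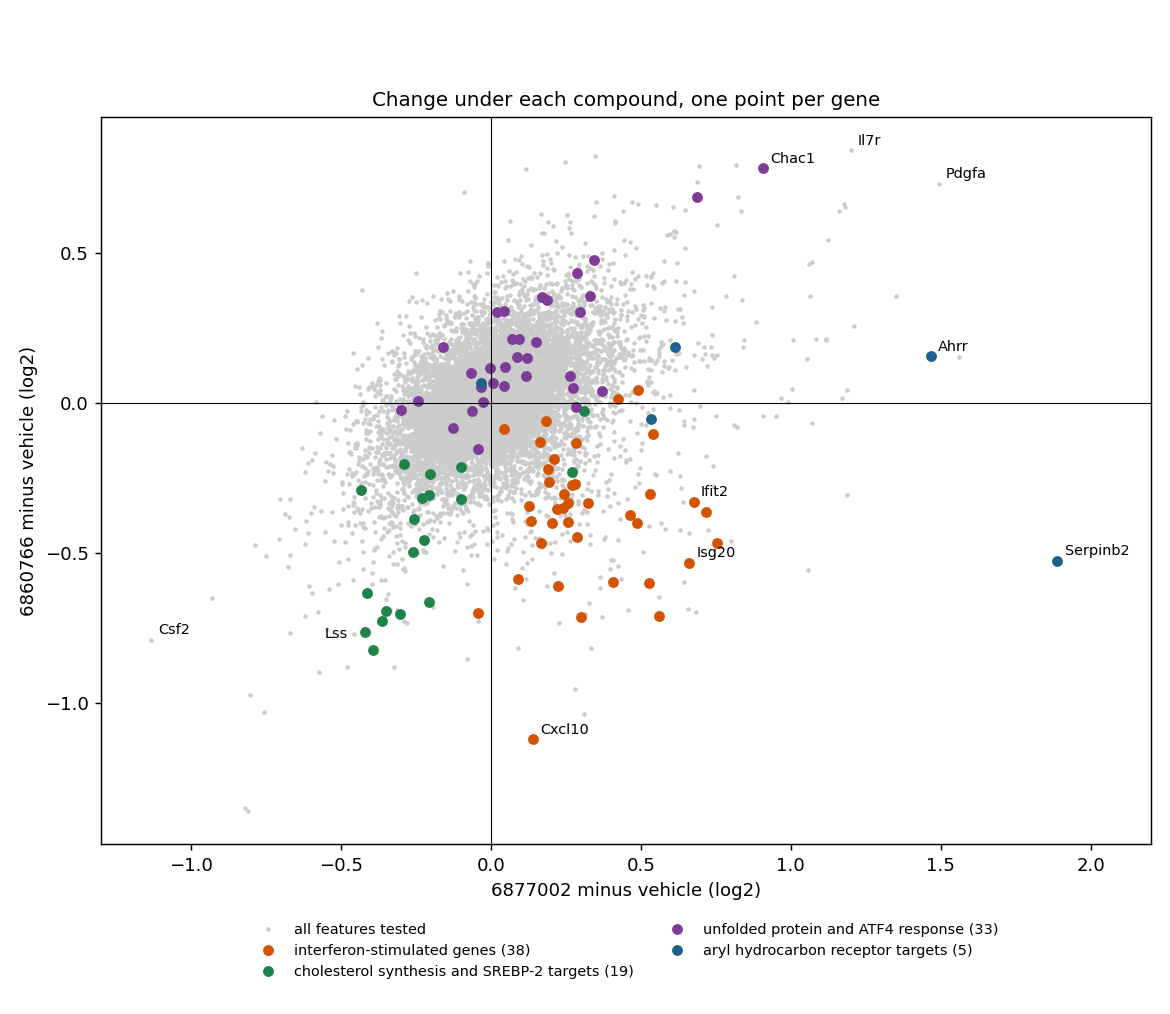
Log2 change of each feature under 6877002 (horizontal axis) and under 6860766 (vertical axis), both against the same 3 vehicle arrays, with 4 gene lists in colour. Interferon-stimulated genes such as Isg20 (0.66 and -0.53) lie at lower right, and cholesterol synthesis genes such as Lss (-0.42 and -0.77) at lower left.

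Genes near the receptor moved little. Of 23 tested CD40, TRAF and NF-kB components, 0 passed under 6877002 (mean -0.0048, camera adjusted p = 0.615), 2 fell under 6860766 (mean -0.054, 0.128) and 2 were higher with 6877002 than with 6860766 (mean 0.050, 0.378), with 1 rise, 3 falls and 3 rises adjusted over the list alone. Cd40 itself changed by -0.20 ± 0.06 under 6877002, which did not pass limma (adjusted p = 0.097), and by -0.28 ± 0.06 under 6860766 (adjusted p = 0.014 in limma, 0.089 without vehicle replicate 2, and from 0.0060 to 0.180 over 31 alternatives). For Traf6, the adaptor the compounds were made against, the changes were -0.06 ± 0.07 and -0.01 ± 0.07, for Traf1 0.01 ± 0.08 and -0.08 ± 0.08, and for Traf5 -0.05 ± 0.15 and -0.04 ± 0.15 under 6877002 and 6860766. Inflammatory genes fixed in advance differed. The changes were -0.0027 ± 0.07 and -0.11 ± 0.07 for Tnf, 0.01 ± 0.06 and 0.03 ± 0.06 for Il1b and -0.35 ± 0.21 and -0.65 ± 0.21 for Il6. They were 0.18 ± 0.09 and -0.10 ± 0.09 for Ccl2 and -0.05 ± 0.06 and -0.07 ± 0.06 for Ccl5. None of these genes passed limma (adjusted p from 0.128 to 0.987). Nos2 and Cxcl10, from the same fixed set, did: Nos2 rose under 6877002 and Cxcl10 fell under 6860766, as given above. Il1b lay at 14.08 to 14.23 on the arrays, with 9 to 35 of 11406 features brighter, so near the top of the scale that its values say little about change. Ccl5 (13.79 to 14.00, 49 to 82 brighter) and Tnf (13.51 to 13.81, 81 to 140 brighter) also lay high, and the same caution holds for them. For Ccl2 the range was 12.96 to 13.48, with 147 to 262 brighter. The mannose receptor Mrc1 (-0.01 ± 0.09 and 0.07 ± 0.09) and the haem oxygenase Hmox1 (-0.02 ± 0.08 and -0.01 ± 0.08) did not pass either. Traf2, Traf3, Il10, Il12b and Arg1 were not analysed here.

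The other lists did not shift in camera under 6877002, under 6860766 or between the compounds. Leukocyte adhesion and migration genes averaged 0.040, -0.025 and 0.065 over 25 members (adjusted p 0.60, 0.518 and 0.309), LXR and lipid genes 0.0036, 0.018 and -0.014 over 22 (0.767, 0.637 and 0.921), NRF2 targets 0.016, 0.053 and -0.037 over 28 (0.922, 0.345 and 0.347) and heat shock genes 0.079, -0.034 and 0.11 over 21 (0.553, 0.313 and 0.129). For alternative activation markers the camera means were -0.027, 0.013 and -0.040 over 15 (adjusted p 0.803, 0.494 and 0.446), for p53 and apoptosis genes 0.034, 0.021 and 0.013 over 23 (0.271, 0.903 and 0.309), for proteases 0.092, 0.095 and -0.0023 over 24 (0.308, 0.313 and 0.815), for immediate early genes -0.038, -0.0065 and -0.032 over 23 (0.677, 0.466 and 0.894) and for osteoclast genes 0.061, 0.14 and -0.078 over 12 (0.60, 0.128 and 0.465). Macrophage identity genes averaged 0.063 and -0.058 against vehicle (camera adjusted p 0.104 and 0.128), antigen presentation genes -0.052 under 6860766 (0.058), aryl hydrocarbon receptor targets -0.034 under 6860766 (0.985), cell cycle genes -0.036 and NF-kB targets 0.041 under 6877002 (0.276 and 0.492), and glycolysis genes 0.0031 between the compounds (0.806). By fry, macrophage identity genes passed under 6877002 and under 6860766 (adjusted p 0.0039 and 0.011), and CD40, TRAF and NF-kB components passed under 6860766 (0.013). In LXR, p53, osteoclast, NRF2 and cytokine genes under 6877002, in aryl hydrocarbon receptor and immediate early genes under 6860766, and in LXR, glycolysis, protease and immediate early genes between the compounds, the list's mean, median and test differed in sign.

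Some members of these lists passed on their own. Plin2 rose by 0.61 ± 0.09 under 6877002 and 0.65 ± 0.09 under 6860766, Plau by 0.82 ± 0.10 and 0.79 ± 0.10, and Plk2, a stress-induced kinase, by 0.45 ± 0.08 and 0.49 ± 0.08. Axl rose under 6877002 (0.56 ± 0.08), while the lipid receptor Trem2 (0.40 ± 0.08) and the beta-glucan receptor Clec7a (0.49 ± 0.10) rose and the fatty acid desaturase Scd1 (-0.64 ± 0.08) and the chaperone Hspa1a (-0.62 ± 0.08) fell under 6860766. Each passed limma whichever array was left out. Under 6877002 Scd1 also fell and Hspa1a rose in limma, but neither of these calls held whichever array was left out. Ahrr and Nqo1 changed by 0.16 ± 0.11 and -0.05 ± 0.13 under 6860766, where neither passed limma (adjusted p 0.610 and 0.926).

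Markers of other cells were few. Neutrophil genes averaged 0.058, -0.0045 and 0.063 over 11 members, with 0 passing in any comparison (camera adjusted p 0.713, 0.539 and 0.330; at most 1 fall adjusted over the list alone). T and NK genes averaged 0.31 (0.064 to 0.55), 0.15 and 0.15 over 5 members (camera adjusted p 0.128, 0.313 and 0.330), and under 6877002 they passed limma's fry (adjusted p = 0.023). Their member Cd28 rose under 6877002 (1.06 ± 0.12) and was 0.60 ± 0.12 higher with 6877002 than with 6860766. Its rise under 6860766 (0.46 ± 0.12, adjusted p = 0.035 in limma) had adjusted p from 0.012 to 0.434 over 31 alternatives and did not pass with mouse as a block (0.053), nor without vehicle replicate 2 or 3, 6860766 replicate 1 or 2, or any array of 6877002 (0.053 to 0.158). Too few were tested for camera in B and plasma cells (3 tested, 0 passed limma in any comparison), dendritic cells (4, of which Tcf4 passed under 6860766 and between the compounds), fibroblasts (1, 0 passed), mast cells and basophils (2, of which Hdc passed under 6860766 and, at 0.77 ± 0.09, between the compounds) and erythroid cells and megakaryocytes (2, 0 passed). Tcf4 changed by -0.32 ± 0.08 under 6860766 (adjusted p = 0.028 in limma, and 0.0083 to 0.708 over 31 alternatives) and did not pass without vehicle replicate 1 or 2 or 6860766 replicate 1 or 2 (0.068 to 0.162). Between the compounds Tcf4 differed by 0.34 ± 0.08 (0.011 in limma, and 0.0022 to 0.287 over 30 alternatives) and did not pass without 6860766 replicate 1 or 6877002 replicate 1 or 2 (0.054 to 0.077). Housekeeping genes averaged -0.076, -0.014 and -0.062 over 13 members (camera adjusted p 0.104, 0.454 and 0.330) and passed fry under 6877002 (adjusted p = 0.023), with 1 of 13 positive.

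Some of these short lists passed limma's fry. B and plasma cell genes were lower with 6877002 than with vehicle (mean -0.23, -0.35 to -0.10, adjusted p = 0.0096) and than with 6860766 (-0.19, -0.32 to -0.067, 0.016), with 0 of 3 members positive. Erythroid genes passed fry under 6877002 (mean -0.26, -0.37 to -0.14, adjusted p = 0.045) and dendritic genes under 6860766 (-0.23, -0.37 to -0.093, 0.016). Mast cell genes passed fry under 6860766 (-0.23, -0.42 to -0.043, 0.016) and between the compounds (0.19, 0.0072 to 0.38, 0.026). Lists of 2 to 5 genes are too short to speak for a kind of cell.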

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

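Slide as a block, median scaling, cyclic loess, no background correction and leaving out each array were fixed in advance. Their use here as tests of slides, of scaling and of a mislabelled array, with the criteria, was chosen only after the result was seen. Interferon-stimulated genes stood out because the compounds differed in direction against the same vehicle arrays. In limma 31 features were higher under 6877002 and lower under 6860766, of which 11 were on the interferon list and 3 had no symbol. Over the 38 tested genes of the list the mean difference between the compounds was 0.70, with 6877002 higher in 3 of 3 mice (adjusted p = 6.13e-66 in camera, and at most 0.016 over 30 alternatives).

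A difference between slides is argued against as the whole cause: with slide as a block the list mean was 0.25 under 6877002, -0.36 under 6860766 and 0.61 (95% confidence interval 0.49 to 0.74) between the compounds, and it was 0.62 within slide 3, which held both. Scaling between arrays is argued against too. Under median scaling and cyclic loess, in both comparisons with vehicle, the list mean at its lowest was 0.919 of its size (median scaling, 6877002). Without background correction, which kept the same quantile scaling, it was at least 0.839. A pattern carried by 1 array, such as a mislabelled one, is also argued against. With any 1 array left out the list mean kept at least 0.878 in all 3 comparisons, though an array in neither group compared cannot move it. An exchange of labels between arrays was not tested. The rise under 6877002 is the less certain side, because camera with an estimated correlation gave it an adjusted p of 0.085, the highest of 30 alternatives. An opposite action of the compounds on interferon signalling is a candidate explanation and remains a hypothesis, found and examined on the same 9 arrays. Unequal doses, which the labels do not give, were not tested.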

How the results depend on the processing

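The alternatives on the slide set, on slides 3 and 4 or 1 and 2 alone, and without the 2 arrays apart from their groups on the first component (vehicle replicate 3 and 6860766 replicate 3), and the glycolysis list without Pigq and Eno1b, which changed no list call, were chosen after seeing the data. Counts of genes follow in the order 6877002 against vehicle (A), 6860766 against vehicle (B), 6877002 against 6860766 (C) and F test (F), which were 341, 328, 516 and 691, where an alternative moved them by more than 1.5 times. Median scaling gave 207, 167, 307 and 456. Array weights gave 627 for A, 1132 for C and 1225 for F, and the 6 arrays compared alone gave 613 for A. An adjusted p under 0.10 gave 603 for A and 776 for C, by its construction. The slide set as a block gave 194 for A, and slides 1 and 2 alone gave 149 for B. Slides 3 and 4 alone gave 168, 85, 316 and 395, where the lone arrays of vehicle and 6860766 are assumed to vary like the others. Without mouse 1 the counts were 147, 128, 221 and 310, without mouse 2 they were 127, 106, 193 and 264, and without mouse 3 C was 1090. Without the 2 arrays apart they were 754 for A, 1119 for C and 1371 for F. Without 1 array A ran from 167 (6877002 replicate 1) to 653 (6860766 replicate 3), B from 168 (vehicle replicate 2) to 467, C from 315 (6877002 replicate 1) to 1062 (6860766 replicate 3) and F from 458 to 1248 (the same 2 arrays), and r between the compounds from 0.220 to 0.507. Apart from the looser threshold, the cause was not tested.

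With mouse as a block, which follows the pairing read from the labels, the counts were 341, 335, 497 and 668, with 306, 300 and 479 of the same genes in A, B and C. Of 481 named gene results the block ended 13 calls and added 9, and it changed no other call. Camera with an estimated correlation kept 3 of 6 lists in A, 5 of 8 in B and 6 of 9 in C, and without 1 array 5 to 6, 7 to 10 and 9 to 10 passed. None of the 23 called list results changed sign in its 30 to 32 alternatives, but the mean of aryl hydrocarbon receptor targets without background correction was 0.55 in A and 0.56 in C, against 0.89 and 0.93. Of the named genes 1 called value changed sign: Pfkl in A was 0.054 over the mean of its probes and -0.29 for its brightest probe, and the cause was not tested. Calls of named genes ended in 101 cases under median scaling, 74 with slide as a block, 42 with the mean of probes, 145 on slides 3 and 4 and 9 to 71 without 1 array, and in 0 with the authors' values. Every probe tested singly gave no list result, and the 6 arrays compared gave no F test and no r. Between 33.7% and 35.2% of probes had signal over background on an array, and genes under it were not measured.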

Other observations

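The families in this part, the tests of the slide set and the splits within mice were chosen only after the values were seen, and so were the criteria for the other splits and for the tests of slides and vehicle arrays, which use slide as a block and the left-out arrays fixed in advance. The PYHIN family, interferon-inducible sensors of DNA, had 3 rises among 8 tested members under 6877002 (Ifi205, Ifi213 and Ifi214) and 5 falls under 6860766 (the same 3, Ifi207 and Mndal), and 7 members were higher with 6877002 than with 6860766. Its mean was 0.40, -0.47 and 0.87 in these comparisons and kept its sign under median scaling, cyclic loess and no background correction. Of 9 guanylate-binding and immunity-related GTPases, which attack the vacuoles of intracellular pathogens, 7 were higher with 6877002 than with 6860766 (mean 0.59, and 0.48 to 0.60 under these alternatives). Of the GTPases Gbp2, Gbp3, Gbp5, Igtp and Irgm1 also stand on the interferon list, so that family is not separate evidence from it. Of the PYHIN members 0 stand on that list. The PYHIN family is interferon-inducible and was picked on the same arrays, so it is not independent evidence either.

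Among 5 tested P2Y nucleotide receptors, P2ry13 and P2ry14 rose under 6877002 and were higher than under 6860766. The family mean was 0.53 under 6877002 and -0.0095 under 6860766, where it changed sign between the same alternatives (-0.022 to 0.041). Of 22 kinesins, motors of the spindle and of transport, Kif18b, Kif22, Kif23 and Kif2c were lower with 6877002 than with 6860766 (mean -0.17, and -0.22 to -0.10 under those alternatives). Of 7 regulators of G protein signalling Rgs1 alone passed, with a rise under each compound. The families were picked because members had changed, so no test of their means is given, and single arrays were not left out for them.

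Cholesterol synthesis genes were lower under both compounds. A difference between slides is argued against as the whole cause, since with slide as a block the list mean was -0.42 under 6860766 and -0.16 (95% confidence interval -0.30 to -0.02) under 6877002. A single high vehicle array is argued against too, because without any 1 of them at least 0.959 of the mean fall and the camera call stayed. Lower activity of SREBP-2, the factor that drives these genes, is a candidate explanation that was not tested. Under 6877002 the call is less certain, as camera with an estimated correlation gave an adjusted p of 0.115, the highest of 30 alternatives.

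All 6877002 arrays lay on slides 3 and 4, and arrays of slides 1 and 2 and of slides 3 and 4 took opposite signs on the first component. With this slide set as a block 165 of the 341 genes called between 6877002 and vehicle still passed limma. Over all 341, log2 changes with the block were a median 0.902 of those without it (5th percentile 0.634, 95th 1.21, with 1 gene under 0.5) and standard errors a median 1.17, so the slide set is argued against as the whole cause. Over the 176 that no longer passed the ratios were 0.816 and 1.16, and the block took the residual degrees of freedom from 6 to 5; which of these ended a call was not separated. A smaller share from the slide set may remain in single genes.

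Other splits of the arrays were counted for each result. For the F test, 1 of 100 splits drawn from 280, the real one, gave as many as 691 genes, and the highest other gave 209. These splits move arrays between mice, but of the 36 that keep 1 array of each mouse in every group again 1, the real one, gave as many. The highest other gave 209 (668 and 139 with mouse as a block). Shares of 1 in 100 and 1 in 36 argue against chance and do not exclude it, and 1 in 36 is the smallest share those splits can give. They also do not separate the compounds from the slides. Of the 100, 2 of the 3 others over 100 genes kept the 6877002 arrays together. Those arrays all lay on slides 3 and 4, so these splits cannot tell the compound from the slide set. For pairs of groups the 10 splits are too few for a share under 0.05. The real and highest other counts of genes were 341 and 0 for 6877002 against vehicle, 328 and 8 for 6860766 against vehicle, and 516 and 1 for 6877002 against 6860766, each reached by 1 split. For lists they were 6 and 6, 8 and 8, and 9 and 7, reached by 2, 2 and 1 splits. Against vehicle the number of lists passing camera therefore does not set the real grouping apart from the other splits. Of the 4 splits that part all 3 pairs of a mouse, the other 3 gave at most 0, 0 and 1 genes and 6, 3 and 7 lists in the same order. The other split with 6 lists kept both slide 4 arrays together and both slide 3 arrays together, and with slide as a block 7 lists passed, 5 of them among the 6. The other split with 8 lists followed no slide, and the one with 8 genes set all slide 1 arrays against the rest, where with slide as a block 311 genes passed.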
